A study of Mus musculus with 2 samples.

How the data were processed

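The series holds ATAC-seq of whole newborn mouse intestine (age 0 days) in 2 biological replicates of 1 group. Replicate 1 pooled the intestines of 15 mice and replicate 2 an unstated number, with males and females pooled in both. Per the labels, DNA was fragmented by Nextera tagmentation, the fragment size range was 200 to 750 bp, and the assembly was mm10. The aligner, the peak caller and their versions are not given in the sources used here.

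Each deposited list gives accessible regions on mm10 with 1 line per summit. The deposited score of each line runs up to 1000, as scaled by the authors. The deposited signal is the authors' own enrichment value of each peak, and its scaling is not stated, so signals were compared only within and between these lists. The deposited -log10 values give the p and q of each peak, and in the ranked lists also the local and global irreproducible discovery rate, a measure of how well a peak's rank repeats between replicates. Per the deposited notes, thresholded, pseudoreplicated and replicated lists derive from filtered alignments and 1 further file whose role is not stated, and ranked lists from the alignments alone. Each replicate has a thresholded, a pseudoreplicated and a ranked list. The series has a conservative thresholded list, a further thresholded list, a replicated list, a pseudoreplicated list and 2 ranked lists. The conservative list was checked to be 1 ranked list at a global rate of 0.05 or less, less 244 lines. The 8 columns per ranked list that hold the values of each input, 32 in the 4 ranked lists, were not used.

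Lines with the same coordinates were merged into 1 region with the summit and signal of the strongest line. Positions are counted from 1. All 1077350 lines on main chromosomes lay within the chromosome ends of GRCm38.p6, the assembly of mm10. Genes and start sites came from GENCODE M21, with 21853 protein-coding genes and 54327 start sites. Read counts are not in the files, so depth is unknown and no limit of detection can be given. Precision rests on the number of regions, and 95% Wilson intervals cover counting error only.

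Replicate overlap was the share of a replicate's regions overlapped by the other replicate over at least 50% of the shorter region, with 100 circular shifts within chromosomes as the chance level. Signal concordance was the correlation of log2 signal across shared regions. Regions restricted to a replicate had no overlap in the other's ranked list. Summits were assigned to promoter (within 1000 bp of a start site), exon, intron or intergenic DNA, in that order, and compared with the share of the genome in each class. No test across the 2 replicates was made. Values per replicate came from each replicate's own thresholded list and are given as mean and SD where both had a value.

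The gene lists, 37 in all with 454 genes, were fixed before the data were examined, as were the consensus sequences and the rules for calls. They cover epithelial transcription factors, general epithelium, enterocytes of the suckling and mature stage, secretory, stem and regional genes, cells of the gut wall and blood, neighbouring organs, Hedgehog, Notch, housekeeping and Hox genes, and 8 comparison tissues. A gene counted as accessible at its promoter when a region lay within 1000 bp of any of its start sites. Its promoter signal was that of the strongest such region, taken in each list apart. Positions and distances of promoter regions are those of the conservative set, and a replicate's value can come from another start site. The number of accessible genes was set against 10000 random lists of protein-coding genes of the same size, matched on the decile of promoter CpG observed over expected. CpG was taken around the 5' end of each gene, also where a region lay at another start site. The number of start sites per gene was not matched. The distal measure was the median number of regions centred within 50000 bp of a gene's 5' end and not within 1000 bp of its own start sites. Promoter regions of neighbouring genes were therefore counted. This median was set against random lists matched on local gene density and CpG quintile. Permutation p values are two-sided and were adjusted by Benjamini and Hochberg over the 37 lists, with a threshold of 0.05. Prac1 was not in the annotation, and Cblif was found under its older name Gif. Members of the Defa, Hba, Hbb and Serpina1 families have near-identical neighbours, so their values are uncertain.

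For 24 consensus sequences, the number of distal summits with the string on either strand within 50 bp was set against windows of the same width centred 500 bp to either side. With a pseudocount of 0.5, a consensus was called when the log2 ratio was above 0.2 in both replicates' lists and above that of its reversed, not complemented, string. Distal summits here lay over 1000 bp from any protein-coding start site, and there were 15413 in replicate 1 and 13945 in replicate 2.

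Named genes followed a fixed rule. In each list it takes up to 4 genes with the highest promoter signal and up to 4 in alphabetical order with none. It also takes the 10 strongest regions outside and 5 within promoters, the 15 genes with the most distal regions, all Hox genes and 26 intestinal and other marker genes.

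The methods were tested on simulated data. Of 20 lists simulated with raised accessibility, 18 were called at promoters and 20 by distal regions, and of 20 simulated without, 0 were called by either. Each simulated list had 15 genes. The raised lists were drawn from genes of low promoter CpG content alone and were given a large rise. They do not show how often a rise would be found in smaller lists, in CpG-rich genes or where it is weaker. All 3509 simulated shared regions were found. For the consensus rule, 6 of 6 planted strings were called. Among 18 strings that were not planted, 3 were called when centre and flanks had equal base composition before planting (CArG, RUNX and TCF/LEF). With base composition as in the data, 5 were called (CArG, E-box, NFI, NRF1 and TCF/LEF). Bases were shuffled singly, and each planted string was put into 10% of the same centre windows and not into flanks. How far planting made these calls was not tested. Earlier, smaller versions of this simulation, which did not require a call in both replicates, had called 6 to 8 of the 18. The rule is thus not free of false calls.

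Alternatives were the other lists of the series, replicated peaks, the upper 50% of regions by signal, each replicate's list alone, other overlap rules, promoter windows, distal windows and summit windows, the gene's 5' end alone, unmatched random lists or Fisher's exact test, shuffled sequence and promoter summits. Chosen after seeing the data were Fisher's exact test against the pooled comparison tissues, overlap with the other replicate's ranked list, overlap of the 20000 strongest regions of each replicate, summits without the HNF4 consensus, and list sizes without a replicate. Regions were compared with mitochondrial DNA and with the assembly by BLAST 2.17.0 (E of 1e-05 or less, at least 50 bp, 90% identity). Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and pysam 0.24.0, with matplotlib 3.10.9 for figures.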

Results

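Chromatin accessibility was measured by ATAC-seq in whole intestine of newborn mice (age 0 days, B6NTac;B6NCrl/Lap, males and females pooled). ATAC-seq marks open DNA by the insertion of sequencing adapters by the Tn5 transposase. The series holds 1 group with 2 biological replicates. Replicate 1 came from the intestines of 15 mice, and the number of mice in replicate 2 is not given. The deposited lists of accessible regions carry no read counts, so the depth of each replicate is unknown. With 1 group there is no contrast between conditions. The comparisons implied by the design are between the replicates, between the accessible regions and the genome, between gene lists and matched random genes, and between region centres and their flanks. The labels state no further question.

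The newborn intestine had 32325 accessible regions in the conservative set, the regions that passed the authors' irreproducibility threshold across both replicates. They covered 0.917% of the mm10 genome, with a median width of 733 bp, and 63.4% of them held several summits. The replicates' own thresholded lists held 26443 regions in replicate 1 and 24566 regions in replicate 2.

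The replicates shared most of their accessible regions and ranked them alike. Of the regions of replicate 1, 80.7% were overlapped by a region of replicate 2 (95% Wilson interval 80.2 to 81.2), and of the regions of replicate 2, 88.03% were overlapped by replicate 1 (87.6 to 88.4). The mean was 84.4%, against a mean of 0.894% and a highest value of 1.11% after 100 random shifts of positions along the chromosomes. The SD of the 2 shares, 5.19, is not a spread between replicates, since they are 2 directions of 1 comparison. With the 20000 strongest regions of each replicate, chosen after seeing the data, the shares were 85.4% and 86.0%. Across the 21337 shared regions, the signal of a region in one replicate tracked that in the other with Spearman's rho 0.900 and Pearson's r 0.904 on log2 values. The median log2 difference, replicate 2 minus replicate 1, was 0.03 (SD 0.24), and 99.7% of the shared regions lay within 2-fold. This correlation is across regions, which are not independent replicates, and no p is given. The signal is the authors' own value for each peak, computed for each list apart, so these values describe the lists and not a change in accessibility. In contrast to the signal, the deposited -log10 p of the same regions had a median of 71.5 in replicate 1 and 59.0 in replicate 2.

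**Figure D1:**
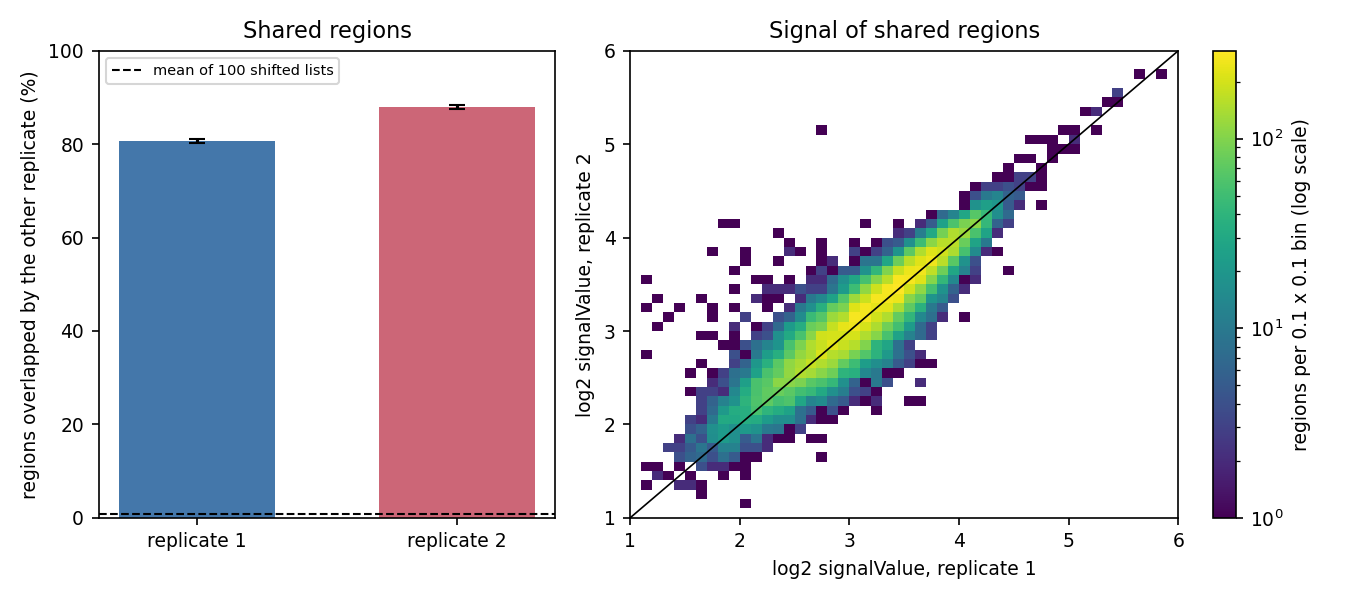
Left, the percentage of each replicate's regions overlapped by the other replicate, with 95% Wilson intervals and the mean of 100 shifted lists as a dashed line. Right, log2 signal of replicate 2 against that of replicate 1 for the 21337 shared regions, shaded by the number of regions. The shares are 80.7% and 88.03%, and rho is 0.900.

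Few regions were restricted to 1 replicate, and those were weak. In replicate 1, 392 regions (1.48%) had no overlap even in the full ranked list of replicate 2. Their median signal was 5.20, against 8.16 for all its regions. In replicate 2, 156 regions (0.635%) had none in the ranked list of replicate 1, with a median signal of 5.16 against 8.48. At promoters lay 67 of the 392 and 17 of the 156. Genes of the 37 lists had 14 and 6 of them within 50 kb, and no list had more than 2. These values compare 1 library with 1 library and were not tested.

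Accessible regions were concentrated at the start sites of protein-coding genes. Of the 32325 summits, 36.6% (95% Wilson interval 36.1 to 37.1) lay within 1 kb of an annotated transcription start site, while 2.44% of the genome does, a 15.0-fold difference. Introns held 29.6% of the summits and 34.4% of the genome, intergenic DNA held 30.5% and 60.1%, and exons held 3.33% and 3.02%. The intron share turned direction in the replicated peaks, at 36.5% (1.06-fold over the genome), and the exon share, 1.10-fold in the conservative set, in both replicates' own lists (0.977-fold and 0.926-fold) and in the upper 50% by signal (0.668-fold). In the replicates' own lists the promoter share was 42.5% ± 1.08 (SD, n = 2), with 26.8% ± 0.681 in introns, 27.8% ± 0.287 in intergenic DNA and 2.87% ± 0.108 in exons. The differences from the genome at promoters, in introns and in intergenic DNA were larger than the spread between replicates. Intervals cover counting error only. At least 1 region lay at the promoters of 11951 of the 21853 protein-coding genes (54.7%). The promoter share depended on how strong the regions were. It was 23.6% among the 67418 replicated peaks, a longer list with weaker regions, and 50.5% in the upper 50% of the conservative set by signal.

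**Figure D2:**
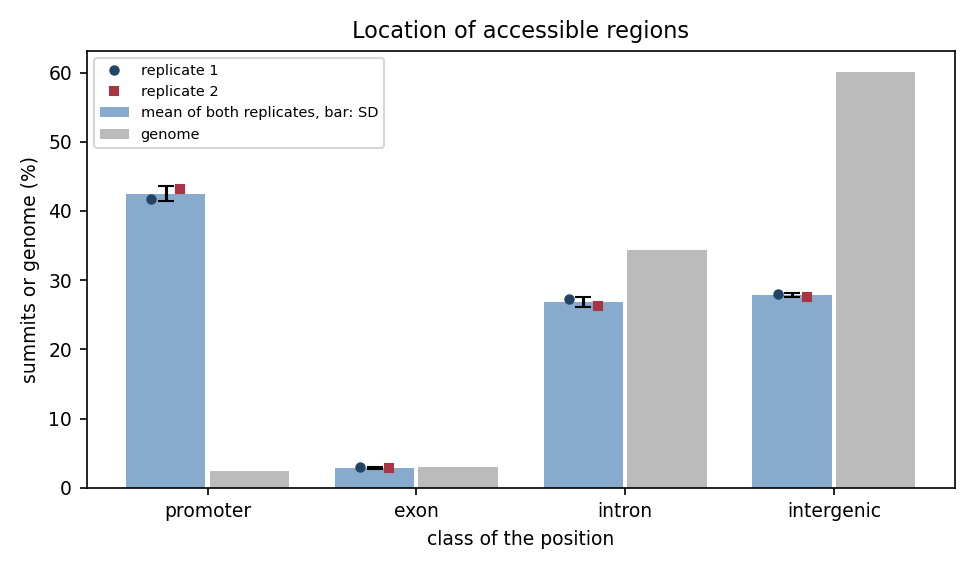
Percentage of summits in each class of position (blue bars, mean of both replicates with SD; points, the replicates) and percentage of the genome in that class (grey bars). Promoters hold 42.5% of the summits and 2.44% of the genome.

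The strongest promoter regions lay at Kifap3 (chromosome 1, 163779294 to 163780115, signal 26.4 in the conservative set), 2610008E11Rik (25.3), Gm49359 (24.8), Zfp960 (24.7) and Tmem218 (24.5). The 10 strongest regions outside promoters reached higher values, from 39.1 to 58.2, and were narrow, with a median width of 305 bp against 613 bp for the other regions outside promoters. The highest lay on chromosome X from 143482935 to 143483180, and its nearest annotated start site, 35531 bp away, was that of Pak3. The next lay on chromosome 2 from 69355469 to 69355735, 12986 bp from a start site of Abcb11. Mitochondrial DNA matched 3 of these 10 regions, on chromosomes 2, 5 and 10, over at least 50 bp at 90% identity or more.

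Genes of the absorptive epithelium, the lining cells that take up nutrients, had the clearest promoter accessibility. In the enterocyte list, 17 of 19 genes had a promoter region, against 6.31 ± 1.78 (SD) in random lists matched on promoter CpG content. Among them were Mttp, which loads lipid onto apolipoprotein B, with a signal of 15.6 ± 1.15 (SD, n = 2), Dgat1, which makes triglyceride, with 9.79 ± 0.962, Vil1, the microvillus protein villin, with 9.11 ± 0.041, and the brush border peptidase Dpp4 with 9.14 in replicate 1 and 8.86 in replicate 2. Alpi, the intestinal alkaline phosphatase, had 5.97 ± 0.094. Fabp1 and Slc15a1 had no promoter region in the conservative set. Each replicate's own list had 16 of the 19.

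Transcription factors of the intestinal epithelium formed the next group, with a promoter region at 17 of 20 genes against 11.4 ± 1.72 in random lists. Klf5 had a signal of 14.6 ± 0.764 (SD, n = 2; chromosome 14, 99298236 to 99299417). Cdx2, which sets intestinal identity, had 10.8 ± 1.01 (chromosome 5, 147306678 to 147307817), Foxa3 had 10.3 ± 1.17 and Ppara, a regulator of fatty acid oxidation, had 9.75 ± 0.686. Gata4 had 9.29 ± 0.307 and Gata6 8.81 ± 0.693. For Gata4 the region of the conservative set lay 25005 bp from the 5' end of the gene, at another annotated start site. Hnf4a had 7.61 ± 2.05. Its region in the conservative set lay 39941 bp from its 5' end, at another start site (chromosome 2, 163546749 to 163547519). For Gata4 and Hnf4a, CpG was matched at the 5' end and not at the start site with the region. Cdx1 had a region in the conservative set and in replicate 2 alone. Creb3l3, Foxa2 and Gata5 had none.

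Genes of the suckling-stage enterocyte, active before weaning, also stood out, with 8 of 10 promoters accessible against 3.91 ± 1.21 in random lists. Dab2, an endocytic adaptor, had a signal of 9.90 ± 0.296 (SD, n = 2) and Prdm1, which encodes the repressor Blimp1, 9.70 ± 0.536. In the conservative set both regions lay at start sites inside the genes, 86446 bp and 69394 bp from the 5' ends, where CpG was matched. The arginine synthesis enzyme Ass1 had 8.88 ± 1.41. Otc, of the urea cycle, had a region in replicate 1 and the conservative set. Lct, which encodes lactase, and Cubn had no promoter region. Of the mature enterocyte genes, which rise at weaning, 3 of 11 had a promoter region, against 3.79 ± 1.32 in random lists. These were Mgam at 6.56 ± 1.37, Slc2a5 at 6.52 ± 0.047 and Treh, which had a region in replicate 2 and the conservative set. Sis, the sucrase-isomaltase gene, had none. Among the replicated peaks the mature list turned to 9 of 11, above random lists at 4.90 ± 1.33 (adjusted permutation p = 0.0407). The suckling-stage and mature lists were not tested against each other.

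All 13 housekeeping genes had a promoter region, against 9.63 ± 1.33, with Sdha at 13.7 ± 0.861 and Polr2a at 12.5 ± 0.585 (SD, n = 2). These were the 4 lists of 37 above random genes. The two-sided permutation p values, adjusted over the 37 lists by Benjamini and Hochberg, were 0.00247 for enterocyte, 0.0116 for transcription factors, 0.0130 for the suckling stage and 0.0308 for housekeeping. The smallest unadjusted value that 10000 random lists allow is 0.0002. Genes are not replicates, so these values describe these libraries. The transcription factor call was lost in each replicate's own list, at 15 of 20 in both (adjusted permutation p = 0.0639 in replicate 2 and 0.0670 in replicate 1). The suckling-stage call was lost without replicate 1, at 6 of 10, in the series' other thresholded list, at 7 of 10, and without matching. The transcription factor and housekeeping calls were lost when the 5' end of the gene alone was used, the housekeeping call also among the replicated peaks, and all 4 calls were lost among the upper 50% of regions by signal, with the enterocyte list at 7 of 19.

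**Figure D3:**
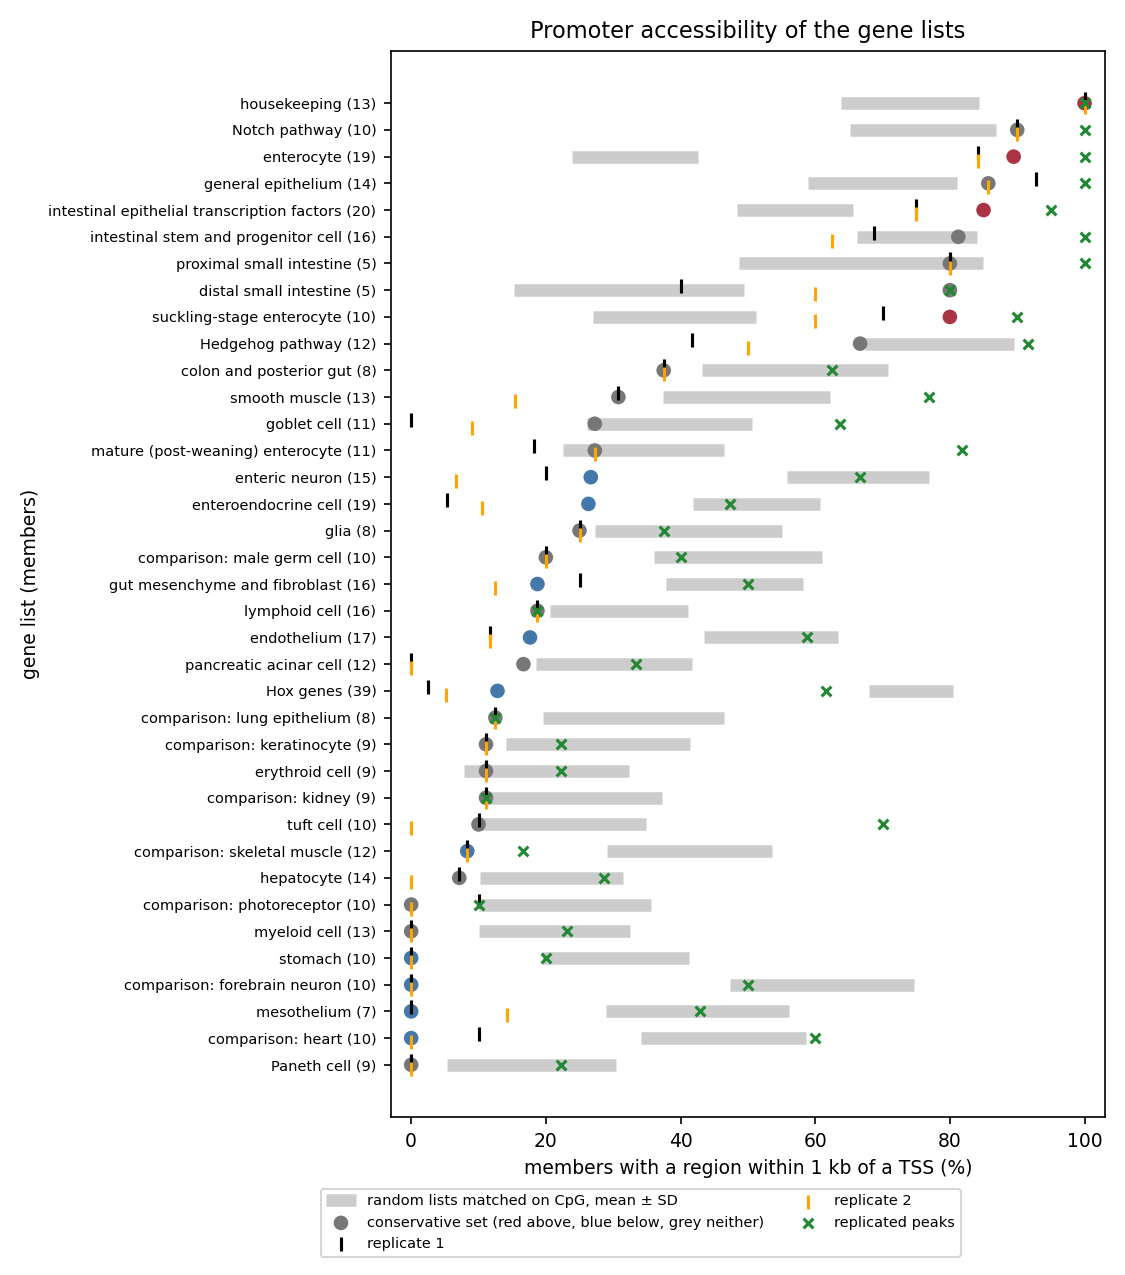
Percentage of the genes of each list with a region within 1 kb of a start site, with the number of genes in brackets. Circles are the conservative set (red above, blue below and grey neither above nor below random lists at an adjusted p of 0.05), ticks the replicates' own lists, crosses the replicated peaks, and grey bars random lists matched on CpG content (mean ± SD). Enterocyte genes reach 89.5% against 33.2% in random lists.

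General epithelial, stem, regional, Notch and Hedgehog genes did not differ from matched random genes in the conservative set. For small or CpG-rich lists a higher call was hard or impossible to reach. With all 10 open in the series' other thresholded list, Notch genes had an adjusted permutation p of 0.129. In the replicated peaks, proximal small intestine at 5 of 5 had 0.625 and stem genes at 16 of 16 had 0.126. General epithelial genes had a promoter region in 12 of 14 cases, led by the adhesion gene Cdh1 at 10.4 ± 0.842 (SD, n = 2), St14 at 9.87 ± 0.446 and the tight junction gene Cldn3 at 8.65 ± 0.144. Stem and progenitor genes had 13 of 16, with Lrig1 at 15.1 ± 1.05, Ephb3 at 13.1 ± 0.933, the Wnt feedback genes Axin2 at 12.3 ± 0.559 and Rnf43 at 11.7 ± 1.39, and with random lists at 12.02 ± 1.43. The crypt stem cell marker Lgr5 had a region in replicate 1 and the conservative set, and Olfm4 in the conservative set alone, 15737 bp from its 5' end. Proximal and distal small intestine each had 4 of 5. The proximal genes included Onecut2 (9.44 ± 1.12), the iron exporter gene Slc40a1 (9.07 ± 0.110) and Pdx1 (8.63 ± 0.309), and the distal ones the bile acid transporter genes Slc51b (10.4 ± 0.095) and Slc51a (6.36 ± 0.221). Colon and posterior gut had 3 of 8, namely Aqp8 (9.46 ± 1.16), Slc26a3 (9.37 ± 1.10) and Satb2 (6.62 ± 0.371), the last 2 with regions 46560 and 8608 bp from the 5' ends. Notch genes had 9 of 10, with Maml1 at 13.4 ± 0.977 and Jag1 at 11.2 ± 0.676, and Hedgehog genes 8 of 12, with Cdon at 16.0 ± 1.66 and Ihh at 7.42 ± 0.054. In the series' other thresholded list the general epithelial genes, at 14 of 14, passed the threshold (adjusted permutation p = 0.0222), as they and the Notch genes did without matching (adjusted Fisher's exact p = 0.0417 and 0.0416). In replicate 1 alone the Hedgehog list, at 5 of 12, fell below random lists (0.0481), as it did in the upper 50% by signal, at 1 of 12 (0.00370). With the 5' end alone, distal small intestine, at 4 of 5, was above and colon, at 1 of 8, below random lists (0.0247 each).

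Of the secretory lineages, enteroendocrine genes fell below matched random lists in the conservative set, and the lists were not tested against each other. Goblet cell genes had 3 of 11 against 4.22 ± 1.34, and of these the mucin gene Muc2 had a region in replicate 2 and the conservative set (in the latter 9272 bp from its 5' end), while Atoh1 and Fcgbp had regions in the conservative set alone. Paneth cell genes, including Lyz1 and Defa17, had 0 of 9, and tuft cell genes 1 of 10, the leukotriene synthase gene Ltc4s. The Paneth list was at the lowest count possible (adjusted permutation p = 0.521), so a lower call was out of reach for it. In the replicated peaks goblet genes had 7 of 11 and tuft genes 7 of 10. Without matching, Paneth and tuft genes fell below all genes (adjusted Fisher's exact p = 0.00330 and 0.0156). Enteroendocrine genes had 5 of 19 against 9.75 ± 1.79 in random lists (adjusted permutation p = 0.0460). The call was lost among the replicated peaks, at 9 of 19, with a 500 bp window (adjusted permutation p = 0.0550) and in the upper 50% by signal (adjusted permutation p = 0.0543), and was kept in each replicate's own list, at 1 and 2 of 19. Chgb had a signal of 7.68 ± 0.812 (SD, n = 2), Isl1, Arx and Pax6 had regions in the conservative set alone, and Neurog3 had none. In replicate 1 the goblet list, at 0 of 11, fell below random lists (adjusted permutation p = 0.0180), which it did not in replicate 2.

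Genes of the gut wall outside the epithelium were less often accessible at promoters than random genes of like CpG content. Endothelium had 3 of 17 against 9.08 ± 1.69 (adjusted permutation p = 0.00444), enteric neurons 4 of 15 against 9.95 ± 1.58 (0.00740), mesenchyme and fibroblasts 3 of 16 against 7.69 ± 1.63 (0.0308), and mesothelium 0 of 7 against 2.97 ± 0.952 (0.0185). The open ones included Esam (10.4 ± 0.745) and Eng (10.3 ± 1.53) in endothelium, Ret, the receptor of enteric neuron precursors (9.04 ± 0.479), and Gli1 (5.00 ± 0.190; all SD, n = 2). In the conservative set the regions of Esam, Eng and Gli1 lay 2066, 26544 and 2810 bp from the 5' ends, at other annotated start sites. With the 5' end alone endothelium had 1 of 17. Pecam1, Phox2b, Col1a2, Col3a1 and Wt1 had none. Smooth muscle had 4 of 13, among them Srf at 10.1 ± 1.04 and Smtn at 8.40 ± 0.406, while Acta2 had none and Myh11 had a region in replicate 1 and the conservative set. Glia had 2 of 8, Entpd2 and Erbb3, with Sox10 at none, and neither of the last lists differed from random genes. The mesenchyme call was lost without replicate 2, at 4 of 16, in the series' other thresholded list, at 6 of 16, and with a 2 kb window, at 4 of 16. The mesothelium call was lost without replicate 1, at 1 of 7, the mesothelium and endothelium calls in the upper 50% by signal, and the enteric neuron call with Fisher's exact test against all genes. Enteric neurons had 3 of 15 in replicate 1 and 1 of 15 in replicate 2, with the call kept in each. Among the replicated peaks all 4 calls were lost, with endothelium at 10 of 17, enteric neurons at 10 of 15, mesenchyme at 8 of 16 and mesothelium at 3 of 7.

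Lists for blood cells and neighbouring organs held few open promoters. Myeloid genes had 0 of 13, and the pan-leukocyte gene Ptprc had none. Lymphoid genes had 3 of 16, namely Pax5 (9.83 ± 1.85, 5608 bp from its 5' end), Tcf7 (7.86 ± 0.479) and Rorc (6.34 ± 0.070; SD, n = 2), and erythroid genes 1 of 9, Klf1. Pancreatic acinar genes had 2 of 12, Cela1 and Rbpjl, hepatocyte genes 1 of 14, Serpina1a, and Alb and Cpa1 had none. The myeloid list was at the lowest count possible (adjusted permutation p = 0.181), so a lower call was out of reach for it. None of these lists differed from matched random genes in the conservative set. The acinar list, at 0 of 12, fell below them in replicate 1, and without matching all 5 lists fell below all genes (adjusted Fisher's exact p from 0.000625 for myeloid to 0.0285 for acinar genes). Stomach genes, such as Atp4a and Atp4b of the acid pump, had 0 of 10 against 3.04 ± 1.09 (adjusted permutation p = 0.0185), a call lost among the replicated peaks, at 2 of 10, and in the upper 50% by signal.

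Lists for tissues not part of the gut served as a comparison and had 6 open promoters among 78 genes (7.69%). Heart had 0 of 10 and forebrain neuron 0 of 10, both below random lists, as was skeletal muscle with 1 of 12, Mylpf. Among the replicated peaks heart turned to 6 of 10 and forebrain neuron to 5 of 10, neither below random lists, and the heart call was also lost in the upper 50% by signal. The skeletal muscle call was lost in 5 of 9 alternatives, namely each replicate's own list, at 1 of 12 in both, the upper 50% by signal, the 2 kb window and the 5' end alone. Photoreceptor had 0 of 10, lung epithelium 1 of 8, kidney 1 of 9, keratinocyte 1 of 9 and male germ cell 2 of 10. None of these differed from matched random lists, though all but male germ cell fell below all genes without matching. The photoreceptor list was at the lowest count possible (adjusted permutation p = 0.283), so a lower call was out of reach for it. Set against these 78 genes rather than random genes, a comparison chosen after seeing the data, 10 of 29 lists were higher and 0 were lower (two-sided Fisher's exact test, adjusted over 29 lists). With only 6 of the 78 open, a lower call was out of reach. Myeloid genes, at 0 of 13, had an unadjusted Fisher's exact p of 0.588. CpG content was not matched there, and stem, Notch and Hedgehog genes, among the 10, had median ratios of 0.713, 0.739 and 0.652 against 0.264 and did not differ from matched random genes. The smooth muscle, mesenchyme, enteric neuron, glia, endothelium and mesothelium lists together had 16 of 76 open (21.1%), an odds ratio of 3.20 (Fisher's exact p = 0.0215). For single lists no lower call was possible, so the lack of one says nothing against the 7 lists called below random genes outside the comparison tissues. That limit does not account for the pooled lists, which were higher than the comparison genes. CpG content was not matched there either (median ratio 0.363 against 0.264), and comparison genes are another reference than matched random genes. With each replicate's own list the odds ratio of the pooled lists was 2.15 (Fisher's exact p = 0.117) in replicate 1 and 1.82 (Fisher's exact p = 0.301) in replicate 2.

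The Hox genes, which pattern the body axis, had few accessible promoters compared with genes of like CpG content. Of 39 genes, 5 had a promoter region against 28.9 ± 2.44 in random lists (adjusted permutation p = 0.00247). They were Hoxa4 (7.17 in the conservative set), Hoxa1 (5.79), Hoxb9 (4.74), Hoxa5 (3.72) and Hoxa7 (3.15), and of the Hoxc and Hoxd genes none had a region. Only Hoxa1 had a region in both replicates' own lists, at 5.80 ± 0.404 (SD, n = 2). Those lists had 1 of 39 open in replicate 1 and 2 of 39 in replicate 2. In the replicated peaks 24 of 39 were open, still below random lists at 33.2 ± 1.89 (adjusted permutation p = 0.00370). Hox genes lie in clusters, while random genes were drawn singly, and these p values do not cover that.

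Distal regions, counted within 50 kb of a gene's 5' end and over 1 kb from its own start sites, were more numerous near 4 epithelial lists. Promoter regions of neighbouring genes count among them. Of the 4 lists, 3 were also called at promoters. Enterocyte genes had a median of 6 distal regions per gene against 0.782 ± 0.690 (SD) in random lists matched on local gene density and CpG content. General epithelial genes, not called at promoters, had 8 against 2.02 ± 0.772, epithelial transcription factors 4.5 against 1.19 ± 0.599, and suckling-stage genes 4 against 0.521 ± 0.620. Creb3l3, a regulator of lipid metabolism with no promoter region, had 12 distal regions in each replicate, and so did Krt18. Cldn3 had 9.5 ± 0.707 (SD, n = 2), Cdh1 had 8.5 ± 0.707, Vil1 had 6.5 ± 0.707 and Cdx2 had 5 ± 1.41. Adjusted permutation p values were 0.00185 for the first 3 lists, the smallest reached in this family of 37 lists, and 0.00888 for the suckling stage. Members of a list that lie near each other count the same regions, while random genes were drawn singly. These p values do not cover that sharing. The suckling-stage call was lost without either replicate (median 2 against 0.309 ± 0.469 without replicate 1 and 2.5 against 0.346 ± 0.495 without replicate 2, with random lists lower as well), the transcription factor and suckling-stage calls without matching, the latter also with a 100 kb window, and all 4 in the upper 50% by signal, where enterocyte genes had 2 against 0.299 ± 0.462 and suckling-stage genes 1.5 against 0.174 ± 0.325.

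Hox genes had fewer distal regions than random genes, a median of 1 against 5.63 ± 0.695 (adjusted permutation p = 0.00185). Promoter regions of neighbouring genes are counted, so this is not a result apart from the few open Hox promoters. Hox genes also lie in clusters and share regions, while random genes were drawn singly, and the p does not cover that sharing. The call was lost with a 20 kb window (1 against 1.85 ± 0.445) and without matching (1 against 1.67 ± 0.650). It was also lost in the replicated peaks (8 against 9.39 ± 0.920). The other 32 lists did not differ. Housekeeping genes, open at every promoter, had a median of 5 against 3.09 ± 0.959 (adjusted permutation p = 0.408), and Notch genes 4 against 1.61 ± 0.781 (0.133). Without replicate 1, the proximal small intestine, Notch and housekeeping lists passed the threshold as well (adjusted permutation p = 0.0444, 0.0326 and 0.0444). Notch genes also did with windows of 20 kb (2.5 against 0.377) and 100 kb (9 against 3.82), and pancreatic acinar genes with 100 kb (adjusted permutation p = 0.00370, 0.0133 and 0.0419).

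Short sequences bound by known epithelial transcription factors were concentrated at the centres of distal regions. The HNF4 consensus CAAAGTYCA occurred in 4.94% ± 0.291 of windows of 50 bp either side of a distal summit and in 0.334% ± 0.009 of flanking windows, a log2 ratio of 3.87 ± 0.05 (SD, n = 2). HNF1 had 2.61 ± 0.05, CTCF, which marks chromatin boundaries, 2.53 ± 0.38, AP-1 2.39 ± 0.09, KLF 2.06 ± 0.09, GRHL 1.95 ± 0.17, GATA 1.76 ± 0.21 and CDX 0.97 ± 0.09. AP-1 was the most frequent of these at summits, at 9.54%, followed by CDX at 6.63% against 3.38% in flanks. Of 24 consensus sequences, 17 passed the fixed rule, a log2 ratio above 0.2 in both replicates and above that of the reversed string. The others were NFI (2.90), NRF1 (2.13), PU.1 (1.52), ETS (1.48), SOX (1.13), TCF/LEF (1.13), E-box CAGCTG (0.86), NFY (0.74) and TEAD (0.69).

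FOXA (0.17 ± 0.04), CArG of muscle genes (0.03 ± 0.13), MEF2 (0.02 ± 0.13), RUNX (-0.01 ± 0.07), OCT (-0.30 ± 0.26) and CRX/OTX (-0.55 ± 0.18; SD, n = 2) did not pass. Nor did the p53 family, whose ratio was 1.32 in replicate 1 and -1 in replicate 2, from 2 and 0 windows. FOXA and p53 family passed in the conservative set and the series' other thresholded list, where no agreement of replicates was asked for, and p53 family also in the replicated peaks and with windows of 100 bp either side. Against shuffled sequence in place of flanks, NRF1 and E-box no longer passed, while FOXA, MEF2, OCT and RUNX did. TCF/LEF, NFI, NRF1 and E-box were also called in simulated sequence where they were not planted, so these 4 calls are uncertain. The centres there held 6 other planted strings that the flanks did not, so those simulated calls cannot be put down to composition alone. NFI occurred in 0.086% of the windows and GRHL in 0.075%, which was 12 windows in replicate 1 and 10 in replicate 2.

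At promoter summits 12 consensus sequences passed, 11 of them among the 17 at distal summits, with OCT the other. In the conservative set, NRF1 had a log2 ratio of 3.40, ETS 3.35, NFY 2.69 and KLF 2.45 at promoter summits. CDX, at -1.02, and GATA, at -0.56, were less frequent at promoter summits than in their flanks. HNF4 had 1.23 at promoter summits and 4.07 at distal ones in the same set. The differences between promoter and distal ratios were not tested.

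**Figure D4:**
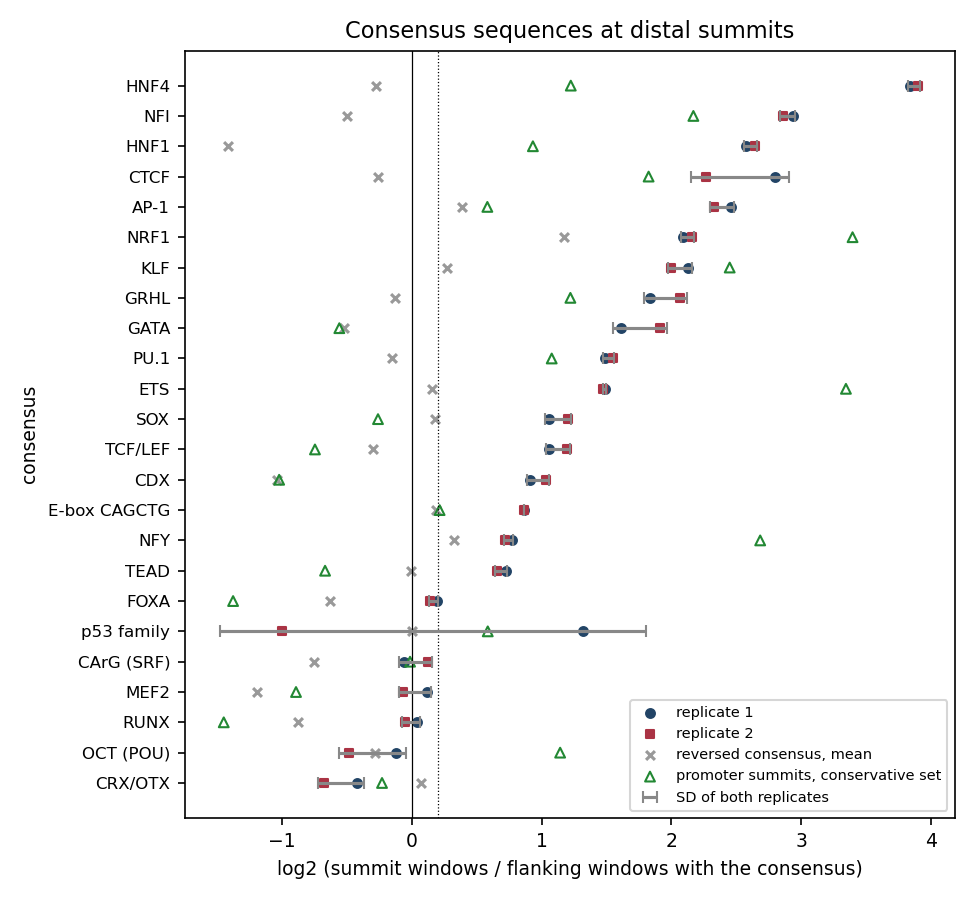
Log2 ratio of the share of windows with each consensus at distal summits to that in flanking windows, for both replicates (circles and squares, bars the SD). Crosses mark the reversed consensus, triangles the promoter summits of the conservative set, and the dotted line the rule's value of 0.2. HNF4 has the highest mean at distal summits, 3.87, and CRX/OTX the lowest, -0.55.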

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

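The test of signal over background and both tests of the gut wall lists were chosen only after the results were seen. The comparison with genes of other tissues, on which the latter rest, was also chosen after seeing the data.

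Lines that passed the irreproducibility threshold but were absent from the conservative set form the 1 result picked out by the fixed rules, as signal in data that no comparison used. There were 244 such lines, in 112 regions. Of these regions, 72 lay on main chromosomes and 40 on other sequences of the assembly. Their median signal was 6.003. For the 72, a median of 36.6% of the length was marked as repeat, and 1 matched mitochondrial DNA. The strongest lay on chromosome 1 from 24611586 to 24616158, 4573 bp wide, with a -log10 p of 10543. It was chosen after its values were seen. All thresholded, pseudoreplicated and replicated lists had 0 lines off the main chromosomes, while the ranked lists had 133 to 222. The absence of the 40 regions is thus shared by all those lists and is not particular to the conservative set. No prediction was written for the 72 regions on main chromosomes, so no explanation is drawn for them.

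The strongest regions outside promoters were narrow and had 1 summit each. Mitochondrial DNA copies in the nuclear genome could account for part of them, since 3 of 10 aligned to the mitochondrial genome and all 14 such regions of the 32325 lay outside promoters. The other 7 had 0 alignments at any identity, so diverged mitochondrial copies are argued against for them. Repeats stay open, as the median masked share was 22.5% against 9.77% in other regions outside promoters. Near-identical copies elsewhere were found for 2 of 10 and for 0 of 100 control regions. Those 2, on chromosomes 5 and 10, are among the 3 with a mitochondrial match, and the mitochondrial genome was counted as another place. The copies are thus not evidence apart from that match. The other 7 had 0 such copies, which argues against near-identical copies for them. The masked share and the 2 of 10 fall between the bounds set in advance. No biological explanation was tested, since the design gives no second group.

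At equal signal, -log10 p was lower in replicate 2. A lower signal over background in replicate 2 stays open. The median log2 difference of signal, 0.0301, restates the pattern, and each list has its own scaling. Fewer reads in replicate 2 is a candidate explanation. The median log2 difference of -log10 p was -0.26, -0.29, -0.29 and -0.30 over the quartiles of signal, so that highest minus lowest was -0.043, as a common scale factor would give. Read numbers are not in the files, and no biological explanation was tested.

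Few promoters of the mesenchyme, enteric neuron, endothelium and mesothelium lists were accessible compared with random genes. Whether the matched random genes are mostly open in every tissue stays open. With smooth muscle and glia, which did not differ from random genes, the odds ratio against genes of other tissues was 3.20, but its counts were known and CpG content was not matched (median ratio 0.363 against 0.264). Whether the threshold hides regions open in a minority of cells stays open too, as the odds ratio in the replicated peaks was 3.50 and the genes of other tissues also rose, from 6 to 22 of 78. No biological explanation was tested.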

How the results depend on the processing

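The comparisons with other tissues, the overlap with ranked lists, the overlap of the strongest regions, the summits without HNF4 and the list sizes without a replicate were chosen after seeing the data. Over all alternatives planned beforehand, 629 comparisons of a list were made, of which 554 gave the same call. Where at least 1 of the settings compared had a call, 2 changed side of the random mean, both in the replicated peaks (mature enterocyte genes 9 of 11, heart genes 6 of 10). Lists without a call changed side too, such as tuft cell genes. The cause was not tested. Consensus calls numbered 17 and ranged from 12 to 19 over the alternatives. Counts of restricted regions moved to 401 and 162 with the pseudoreplicated lists.

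The cause was not tested for these values either, except where the alternative itself sets it. Counting each line gave 67437 in place of 32325. Mean overlap was 98.9% with the other replicate's ranked list. Rho was 0.914 for -log10 p and 0.870 in the pseudoreplicated lists. The promoter share was 35.0% in the other thresholded list, 23.6% in the replicated peaks, 50.5% in the upper 50% by signal, 34.0% with 500 bp and 39.9% with 2000 bp, and 41.7% to 43.2% without 1 replicate. Lists above random genes at promoters numbered 4 and became 0 in the upper 50%, 2 to 3 without 1 replicate, and 10 and 15 against other tissues in the conservative set and the replicated peaks. Lists below numbered 10 and became 2 in the replicated peaks, 5 in the upper 50% and 20 with Fisher's exact test against all genes. Against other tissues they became 0 and 0, but in the conservative set no lower call was possible there. By distal regions, lists above went from 4 to 0 in the upper 50% and 2 without matching, and lists below from 1 to 0 in the replicated peaks, with a 20 kb window and without matching. Leaving out a replicate gives no value for overlap, concordance or restricted regions. Depth is unknown, so a promoter without a region was not detected, which does not show that it was closed.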

Other observations

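The tests on HNF4, CDX and CTCF strings near enterocyte genes were set before their results were seen, and the regions named here with an HNF4 string and the epithelial genes without a promoter region were chosen after their values were seen.

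Sex chromosomes had fewer detected regions per Mb than autosomes. A promoter region was present at 342 of 948 genes of chromosome X (36.1%, 95% Wilson interval 33.1 to 39.2) and at 56.0% of autosomal genes (55.4 to 56.7). Chromosome X had 3.77 regions per Mb, autosomes 12.9, and chromosome Y 0.033, with 3 regions in all and no promoter region at any of 183 genes. Among the chromosomes, 11 had the most, with 19.1 per Mb. Mice of both sexes were pooled, and these values were not tested. Neither the number of copies of a chromosome per cell nor how uniquely reads can be placed on it was accounted for. The values therefore do not show a difference in chromatin.

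The genes with the most distal regions lay in gene-dense places. Hist1h1d, of the histone cluster on chromosome 13, Sema3b on chromosome 9 and Vamp2 on chromosome 11 had 19 each. Other histone genes of the cluster, such as Hist1h3e and Hist1h4f, had 18, as did the hyaluronidase genes Hyal1 and Hyal3. Neighbouring genes share these regions, and the promoter regions of neighbours count among them. Among epithelial genes with no promoter region the number varied, with 10 near Fut2, which adds fucose to mucosal glycans, and 9 near the tuft cell gene Avil, but 2 near Sis, 1 near Neurog3 and 0 near Lyz1 and Gcg.

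A few distal regions near absorptive genes carried HNF4 strings at their summits, 4 of 91 near enterocyte genes and 2 of 32 near suckling-stage genes. Here regions at the promoter of any gene were left out. The region on chromosome 1 from 67111643 to 67112211, 11212 bp from the 5' end of the urea cycle gene Cps1, had a signal of 10.3 and the string TGGACTTTG. Others lay near Myo1a (6.18), Slc5a1, the intestinal glucose transporter gene (4.58), and Fabp2, a fatty acid binding protein gene (4.24).

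The hypothesis that such strings gather near enterocyte genes more than near matched random genes was not borne out. For HNF4 the share near enterocyte genes was 4.40% against 4.18% in random lists, percentile 57.18 among 10000. CDX stood at percentile 59.15 and CTCF, included as a string not tied to the cell type, at 54.78. In the whole family of 70 tests, 7 strings by 10 lists, each adjusted p was 1. With 91 summits a difference may have been missed, and not only a small one. AP-1 near general epithelial genes, at 16.67% against 8.27% over 84 summits, reached only percentile 90.7.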
